A study of Mus musculus with 9 samples.

How the data were processed

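Smart-seq2, a full-length cDNA method for small amounts of RNA, was used on spinal cord motoneurons of wild-type mice. Per the labels' protocols, the neurons carried a fluorescent label that the labels call TRDA, and glass electrodes aspirated them from slices of fresh spinal cord 4 weeks after the injury. The labels place 3 libraries in each of 3 groups. They are a sham group, an untrained group with a spinal cord injury, and an SBES group with the injury and synergistic bidirectional electrical stimulation. SBES replicates 1, 2 and 3 were stimulated at 10, 15 and 20 Hz, so each frequency has 1 library and no frequency was tested against another. A difference between single SBES libraries therefore cannot be told from a difference of frequency, and the spread of the SBES group may hold both. The sample titles call the libraries scRNAseq, and the labels give their source as the transcriptome of single cells. The labels also name 3 mice per group, do not tie a library to a mouse and give no number of neurons per library, so whether a library holds 1 neuron or several is not stated beyond the title. The p-values therefore measure the spread between these libraries, part of which may be technical.

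Per the labels' protocols, the authors aligned clean paired-end reads with Hisat2 2.0.1, counted genes with HTSeq 0.6.1 and tested genes with DESeq2. The genome build is mm10, per the submitters' processing notes, and the annotation release and the strand setting of the counting are not given in the sources used here. The authors deposited 1 table of 55401 genes with a column of whole-number counts and a column of FPKM for each library. Per the file headers the second kind of column is FPKM, counts scaled by exonic gene length and by the library total. Recomputing the deposited FPKM from the counts and the exonic lengths gave 100% of the values within 0.006. Of the gene identifiers, 99.5% were in the GENCODE M21 annotation of GRCm38, the assembly called mm10, and 99.4% of these had the same chromosome, start and end. Coordinates below are those of the deposited table. A symbol was shared by more than 1 identifier for 217 identifiers.

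Columns of the table were matched to libraries by name. The names of 5 libraries' columns carry the start of the group's name or the frequency in the title. The columns of the other 4 libraries, the 3 untrained ones and SBES at 10 Hz, were matched by elimination, and every value of those libraries rests on that match.

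Differential expression was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3. The design written before the data were examined provided for limma on FPKM, and for edgeR if the table also held counts, which it did. Genes were filtered with filterByExpr, which left 15893 genes and over 99% of the counts of each library, and libraries were scaled by TMM. All 9 libraries entered 1 quasi-likelihood fit with a coefficient per group and no covariates, so that the groups share an estimate of the spread. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Levels are CPM, counts scaled by the TMM-adjusted library total, with the SD over 3 libraries, and log2 fold changes carry a standard error (SE). Total counts ran from 11821145 to 17675948 per library. PCR copies cannot be told from separate molecules in these counts.

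A set of 45 gene lists covered markers of the cell types a spinal cord sample can hold, cell functions and signs of RNA quality. All were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, with adjustment over the 45 lists of a comparison. Beside each list, camera with an estimated correlation and fry were run, and members were also tested with adjustment over the list alone. Lists share members, so they are not independent of each other. Principal components and correlations used log2(FPKM + 1) of the 11465 genes with an FPKM of at least 1 in at least 3 libraries.

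Named genes follow a rule set in advance. First come up to 8 genes per direction with the largest fold change among those called, with a mean FPKM of at least 5 in the higher group and no overlap between the groups' libraries. Where fewer than 8 passed in a direction, up to 4 genes of smallest unadjusted p with the same limits and an absolute log2 fold change of at least 1 are given as values. Predicted genes, pseudogenes and haemoglobins were left out of this part. To these were added up to 4 members of smallest unadjusted p from each list that passed or that marks a cell type, fixed markers of motor neurons and other cells, and any called member of a list. Some genes that the rule names are not reported here.

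On simulated counts with 200 changed genes among 15893, edgeR recovered 74.6% of genes changed 4-fold in untrained against sham, 71.6% in SBES against untrained and 61.2% in SBES against sham. For genes changed 2-fold it recovered 8.96%, 11.9% and 7.46%, and the share of false calls was 9.92%, 4.88% and 5.26%. Camera recovered the changed list in each simulated comparison and called 0 other lists. These simulations drew each gene separately and shifted every member of that list alike. They therefore do not show how often camera calls unchanged lists when genes are correlated, as in real libraries.

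Alternatives were DESeq2 1.42.0, no filter and a stricter filter, median-of-ratios factors, limma on log2 FPKM with other pseudocounts and scalings, array weights, no mean trend and only the 6 libraries compared. A block for the replicate number, a covariate of glial marker levels, a fold minimum and leaving out each library in turn were run as well. A term for the replicate 1 libraries, a fit without those 3 libraries and other settings of the principal components were chosen after seeing the data. Injury and stimulation share the untrained libraries, so their overlap was set beside 20 simulations of unchanged groups, drawn gene by gene, and beside 100 draws of new group labels for the 9 libraries. The draws were added after seeing the data, keep the correlation between genes and the structure of the libraries, and may hold part of the real differences. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.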

Results

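The study asked how spinal cord injury, and electrical stimulation after it, change gene expression in spinal motoneurons of mice. RNA of labelled, aspirated motoneurons was profiled in 3 sham, 3 untrained injured and 3 stimulated (SBES) libraries, 4 weeks after injury. Total counts were 12641801, 13735840 and 17675948 in sham libraries 1 to 3, 14401284, 15508578 and 15030546 in untrained, and 11821145, 13090902 and 15907743 in SBES. Between 21791 and 23929 genes had at least 1 count.

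Transcripts of neurons were present in each library together with abundant transcripts of other spinal cord cells. Chat, the acetylcholine-synthesising enzyme of motor neurons, averaged 29.6 ± 8.61 CPM (SD, n = 3) in sham, 27.8 ± 6.67 in untrained and 25.9 ± 6.82 in SBES. The median over the 29 motor neuron markers ran from 8.39 to 18.4 CPM per library, that over the 26 pan-neuronal markers from 202 to 394 CPM and that over the 24 oligodendrocyte and myelin markers from 110 to 354 CPM. The pan-neuronal median exceeded the oligodendrocyte median in 4 of the 9 libraries, sham 1 (394 against 254 CPM), untrained 1 (350 against 110), SBES 1 (371 against 210) and SBES 2 (237.2 against 236.7). Mbp, the myelin basic protein gene, took between 3.40% and 6.85% of all counts. The vesicular acetylcholine transporter gene Slc18a3 averaged 99.95 ± 46.8, 74.8 ± 36.1 and 112.5 ± 18.4 CPM in sham, untrained and SBES libraries, Slc5a7 15.0 ± 1.51, 11.6 ± 7.61 and 11.2 ± 6.85, and the peripherin gene Prph 174.5 ± 82.5, 133.9 ± 59.2 and 155.5 ± 43.8. The transcription factors of motor neurons Isl1 and Mnx1 averaged 3.06 ± 0.675 and 3.07 ± 1.37 CPM in sham. None of these markers passed edgeR in any comparison. Median levels of the astrocyte list lay between 159 and 252 CPM, and those of the microglia list between 34.5 and 123.2 CPM.

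The first principal component did not follow the groups. It held 42.3% of the variance and was negative in 3 libraries, sham 1 (-49.1), untrained 1 (-11.4) and SBES 1 (-48.4). On the second component, with 15.9% of the variance, the 3 SBES libraries lay at 9.12 to 24.2 and the others at 4.98 or lower. On the third, with 15.2%, the 3 sham libraries lay at 12.9 to 28.4 and the others at 4.08 or lower. Malat1, a nuclear noncoding RNA, reached 15128, 16069 and 4774 CPM of the total count in those libraries and 514 to 1617 CPM in the others. Mitochondrially encoded genes took 18.6% of counts in SBES 1, 7.36% in sham 1 and 2.47% to 6.27% in the others. The TMM factors of sham 1 (0.727) and SBES 1 (0.760) were the lowest.

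**Figure D1:**
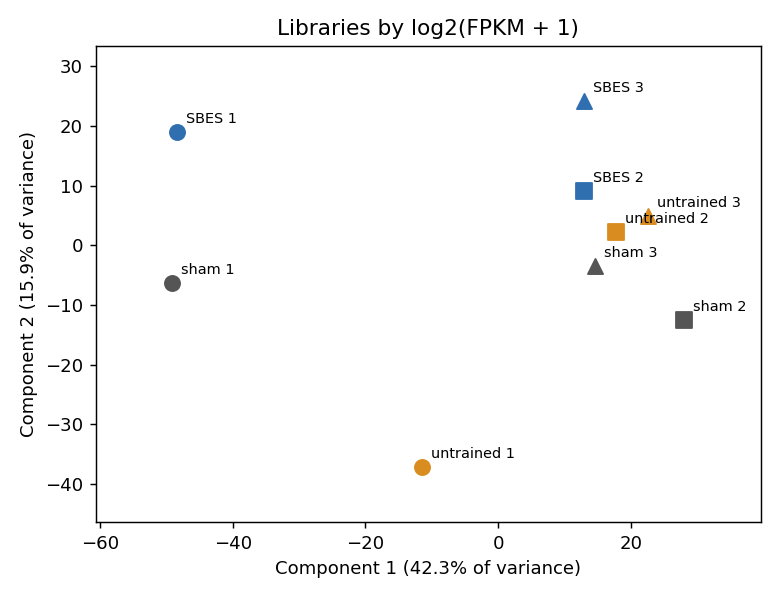
First and second principal components of log2(FPKM + 1) for the 9 libraries, with each axis giving its share of the variance and each point a library named by group and replicate. The replicate 1 libraries of the 3 groups lie at negative values of the first component, and the other 6 at positive values, while the 3 SBES libraries lie highest on the second.

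The comparison of untrained with sham libraries asks what the injury changed. Genes of cholesterol synthesis were lower as a group after injury, with all 25 measured members negative and a median log2 fold change of -0.67 (camera adjusted p = 3.53e-19; adjusted p = 0.328 with an estimated correlation). Endothelial and pericyte markers were higher (median 0.61, 18 of 21 positive; adjusted p = 0.298 with an estimated correlation). Lower as groups were also nuclear-encoded genes of oxidative phosphorylation (median -0.44, 71 of 75 negative), markers of motor neurons (-0.42, 25 of 29), neurofilament and axonal cytoskeleton genes (-0.44, 28 of 31) and oligodendrocyte markers (-0.51, 22 of 24). With an estimated correlation these calls were lost (adjusted p = 0.433 for oxidative phosphorylation and adjusted p = 0.404 for each of the others). Without untrained 1 the motor neuron median was -0.05 (adjusted p = 0.0167) and the oligodendrocyte median -0.23 (0.00676). The oxidative phosphorylation median was -0.10 without sham 1 (0.00585), -0.27 without untrained 2 and -0.66 without sham 2. Interferon response genes were higher (0.47, 25 of 27; adjusted p = 0.188 with an estimated correlation). Of the 45 lists 20 passed camera, and 0 passed with an estimated correlation or with fry. The other splits of the same 6 libraries gave 8 to 20 lists, and 1 of them also gave 20. No single gene was called with edgeR (n = 3 libraries per group), at a smallest adjusted p of 0.184. The count at an unadjusted p under 0.05 was 707, against 794.65 expected by chance, and DESeq2 called 14 genes, 11 higher and 3 lower. The groups' libraries did not overlap for 9.76% of genes, where chance gives 10%. The count of called genes was 4 with a replicate block, 9 with a term for the replicate 1 libraries and 47 without them, the latter fits chosen after seeing the data.

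The genes with the smallest p that met the limits for naming are given as values, since none passed. Higher in untrained libraries were Adm, the precursor of the vasodilator adrenomedullin, at 26.9 ± 7.14 against 7.87 ± 1.94 CPM (log2 fold change 1.76, SE 0.30), and Sult1a1, a sulfotransferase, at 41.3 ± 19.6 against 10.1 ± 3.59 CPM (2.02, SE 0.38). Phyhd1, a dioxygenase domain gene, stood at 1.41 (SE 0.24) and Hrct1 at 1.47 (SE 0.34). Lower were Calca, the precursor of calcitonin gene-related peptide, at 65.9 ± 21.5 against 345 ± 177 CPM (-2.39, SE 0.41), and Cox7a1, a subunit of cytochrome c oxidase, at 5.07 ± 1.93 against 25.8 ± 6.22 CPM (-2.35, SE 0.38). Serpinb1a, a protease inhibitor, was at -1.43 (SE 0.33) and Cox8b, another oxidase subunit, at -1.70 (SE 0.38). DESeq2 gave adjusted p of 0.000199 for Adm, 0.00035 for Sult1a1, 0.000458 for Phyhd1 and 2.1e-05 for both Calca and Cox7a1.

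Within the lists, 0 members rose or fell over all genes tested with edgeR in this comparison, and the counts that follow are adjusted over the list alone. In cholesterol biosynthesis (camera adjusted p = 3.53e-19; adjusted p = 0.328 with an estimated correlation), 8 of 25 fell, among them Mvd (-1.44, SE 0.34) and Dhcr7 (-1.10, SE 0.27). In the endothelium and pericyte list (adjusted p = 5.24e-11; adjusted p = 0.298 with an estimated correlation) 2 rose, the glucose transporter Slc2a1 (0.95, SE 0.26) and the transporter Slco1a4 (1.10, SE 0.31). Calca alone fell in the motor neuron list (adjusted p = 1.16e-08; adjusted p = 0.404 with an estimated correlation), where Uts2b stood at -2.65 (SE 0.75) and Spp1 at -0.96 (SE 0.35). In the oligodendrocyte list (adjusted p = 4.78e-10; adjusted p = 0.404 with an estimated correlation) 1 fell, Ugt8a, which makes the myelin lipid galactosylceramide. In the Schwann cell list (adjusted p = 0.00292; adjusted p = 0.404 with an estimated correlation) 1 of 8 fell, Ngfr, the low-affinity neurotrophin receptor, at 0.285 against 1.19 CPM.

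No member of the other lists that passed camera passed over the list alone. For oxidative phosphorylation the adjusted p was 1.05e-11, and adjusted p = 0.433 with an estimated correlation; its 4 members of smallest p, Atp5e, Atp5d, Atp5h and Atp5g3, lay between -0.79 and -0.64, and between -0.47 and -0.33 without sham 1. For neurofilament and axonal cytoskeleton genes it was 4.78e-10, and adjusted p = 0.404 with an estimated correlation, with Nefl at -0.95 (SE 0.33), Nefm at -1.03 (SE 0.38; -0.53 without sham 1) and Nefh at -1.01 (SE 0.41). The pan-neuronal list, which shares the neurofilament genes, had a median of -0.24 (2.25e-05; adjusted p = 0.456 with an estimated correlation), which was -0.42 without sham 2 and -0.40 without untrained 1. Axonal transport motors had one of -0.23 (0.00282; adjusted p = 0.456 with an estimated correlation), which was -0.11 without sham 1 and -0.13 without untrained 1. Interferon response genes such as Rtp4 (0.86, SE 0.28) and Irf7 (0.96, SE 0.40; 1.47 without sham 3) had an adjusted p of 4.92e-07, and adjusted p = 0.188 with an estimated correlation. MHC class I and complement genes had a median of 0.34 (3.78e-05; adjusted p = 0.456 with an estimated correlation), which was 0.81 without sham 1, 0.15 without sham 3 and 0.23 without untrained 3. Heat shock genes had a median of -0.48 (2.13e-05; adjusted p = 0.123 with an estimated correlation), or -0.29 without sham 1, with Cryab, a small chaperone of glia that the oligodendrocyte list also holds, at -1.29 (SE 0.41).

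The remaining lists of this comparison passed camera with all libraries and lost the call when 1 library was left out. Mitochondrially encoded genes had a median of -0.74 (adjusted p = 0.00578; adjusted p = 0.78 with an estimated correlation), which turned to 0.31 without sham 1 and was -1.18 without sham 2. Without untrained 3 it missed the threshold (0.0596) at a median of -0.72. Cytosolic ribosomal proteins had a median of -0.30 (6.28e-07; adjusted p = 0.621 with an estimated correlation), which was -0.0014 without sham 1 (0.407) and -0.49 without sham 2. The Schwann cell call ended without untrained 1 (0.182), where the median was -0.12 against -0.34 with all libraries and -0.18 without sham 1. Microglia markers had a median of 0.30 (0.00545; adjusted p = 0.66 with an estimated correlation) and the call ended without sham 2 (median 0.12, 0.337), sham 3 (0.08, 0.283) or untrained 3 (0.28, 0.0559), with a median of 0.87 without sham 1. Cytokines and chemokines, at 0.30 (0.00292; adjusted p = 0.468 with an estimated correlation), ended without sham 2 (median 0.17, 0.132) or sham 3 (0.15, 0.0906), with 0.71 without sham 1. The call of the infiltrating leukocyte list was upward, with a median of 0.15 and a mean of -0.06 of opposite sign (0.0105; adjusted p = 0.806 with an estimated correlation), and ended without sham 2 (median -0.30, 0.644), sham 3 (-0.34, 0.926) or untrained 1 (-0.14, 0.182), with 2.02 without sham 1. Ependymal markers, at -0.39 (0.0106; adjusted p = 0.513 with an estimated correlation), missed the threshold without sham 2 (0.132) at a median of -0.34, and ended without sham 3 (-0.13, 0.194), untrained 2 (-0.23, 0.0608) or untrained 3 (-0.15, 0.248), with -0.69 without sham 1 and -0.75 without untrained 1. Apoptosis genes, at 0.21 (0.00292; adjusted p = 0.404 with an estimated correlation), missed the threshold without sham 1 (0.0539) at a median of 0.24, and ended without untrained 3 (0.0571) at 0.09. Their median was 0.37 without sham 2 or untrained 1 and 0.12 without untrained 2. Glycolysis genes, at 0.13 (0.0157; adjusted p = 0.456 with an estimated correlation), missed the threshold without sham 1, sham 3 or untrained 2 (0.0539, 0.0518 and 0.0821) at medians of 0.14, 0.11 and 0.16, and had 0.26 without sham 2.

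The comparison of SBES with untrained libraries asks what stimulation changed after injury. Activity-dependent immediate early genes, which neurons switch on after firing, were higher as a group in SBES libraries, with 28 of 31 positive and a median log2 fold change of 0.57 (camera adjusted p = 4.28e-11; adjusted p = 0.116 with an estimated correlation). Transcripts of other spinal cord cells were abundant in these libraries, and whether the rise came from neurons or from firing was not tested. Interferon response genes were lower, with 24 of 27 negative and a median of -0.38 (adjusted p = 0.116 with an estimated correlation). Without SBES 3 these medians were 0.35 (adjusted p = 1.45e-05) and -0.62 (3.62e-08). Cytosolic ribosomal protein genes were higher (0.31, 71 of 78 positive), as were genes of PI3K-Akt-mTOR signalling (0.26, 22 of 28) and regeneration-associated genes (0.25, 21 of 35). These calls were lost with an estimated correlation (adjusted p = 0.8, adjusted p = 0.485 and adjusted p = 0.8), and without SBES 1 the PI3K-Akt-mTOR call ended (median 0.14, 0.0563) and the regeneration median was -0.04 (0.117). Of the 45 lists 10 passed camera, 0 passed with an estimated correlation or with fry, and the 9 other splits of the same 6 libraries gave 12 to 24. No single gene was called with edgeR (n = 3 libraries per group), at a smallest adjusted p of 0.456. The count at an unadjusted p under 0.05 was 854, 588 higher and 266 lower, against 794.65 expected by chance, and DESeq2 called 29 genes, 22 higher and 7 lower. Libraries of the 2 groups did not overlap for 10.4% of genes, where chance gives 10%. Without the replicate 1 libraries, a fit chosen after seeing the data, 13 genes were called.

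Genes named here by their p are again values, not calls. Setdb2, a SET domain gene of the histone methyltransferase family, stood at 22.2 ± 9.60 CPM in SBES against 1.89 ± 0.146 in untrained libraries (log2 fold change 3.55, SE 0.56). Pdk4, a kinase that inhibits pyruvate dehydrogenase, was at 22.5 ± 13.3 against 3.70 ± 1.43 CPM (2.61, SE 0.49), Phactr3, a regulator of protein phosphatase 1 and actin, at 237 ± 117 against 49.9 ± 26.6 CPM (2.25, SE 0.41) and Ddit4, an inhibitor of mTOR signalling, at 31.4 ± 8.17 against 10.1 ± 3.15 CPM (1.63, SE 0.29). Lower were Gpr34, a microglial receptor (-1.42, SE 0.28), Itm2a (-1.42, SE 0.29), Rtp4 (-1.32, SE 0.29) and the amino acid transporter Slc38a5 (-1.83, SE 0.41). DESeq2 gave an adjusted p of 5.3e-08 for Setdb2, and of 0.00017 for both Pdk4 and Phactr3.

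In the immediate early list (camera adjusted p = 4.28e-11; adjusted p = 0.116 with an estimated correlation), 8 of 31 members rose adjusted over the list alone and 0 over all genes. They included Zfp36 (1.72, SE 0.39), which destabilises cytokine mRNAs, the salt-inducible kinase Sik1 (1.91, SE 0.48), Gadd45g (1.93, SE 0.51) and the clock gene Per1 (1.32, SE 0.36). Gadd45g stood at 365 CPM in SBES 3 and at 88.7 and 68.1 CPM in SBES 1 and 2, and without SBES 3 its log2 fold change was 0.77. In the interferon list (2.37e-08; adjusted p = 0.116 with an estimated correlation) 1 fell over the list alone, Rtp4. No ribosomal protein gene passed over its list alone (2.21e-07; adjusted p = 0.8 with an estimated correlation). Of the PI3K-Akt-mTOR list (0.00295; adjusted p = 0.485 with an estimated correlation) 1 rose over the list alone, Ddit4, and this list's call ended without SBES 1 (median 0.14, 0.0563) or untrained 1 (0.13, 0.054). Of the regeneration-associated list (0.00295; adjusted p = 0.8 with an estimated correlation) 2 rose over the list alone, the small heat shock gene Hspb1 (1.76, SE 0.43) and the transcription factor Cebpd (2.18, SE 0.58), which stood at 1.05 and 0.97 without SBES 3. The call ended without SBES 1, where the median was -0.04 (0.117), and the median was 0.46 without SBES 2.

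The other calls of this comparison were upward and passed camera with all libraries but not without single ones, and 0 of their members passed over the list alone. Mitochondrially encoded genes had a median of 0.68 with 13 of 13 positive (adjusted p = 0.0115; adjusted p = 0.8 with an estimated correlation), which was -0.19 without SBES 1. Without untrained 3 it missed the threshold (0.0879) at a median of 0.57. The pan-neuronal median was 0.31 (0.0158; adjusted p = 0.8 with an estimated correlation) and 0.01 without SBES 1 (0.78), and the call ended without untrained 2 (median 0.17, 0.251) or untrained 3 (0.26, 0.0562). Neurofilament and axonal cytoskeleton genes had a median of 0.28 (0.0266; adjusted p = 0.8 with an estimated correlation), with Nefh at 1.03 (SE 0.41), or 0.57 without SBES 1. Without SBES 1 their median was 0.04 and the direction of the test turned (0.859), and without untrained 1 the call ended (median 0.17, 0.258); without SBES 2 the median was 0.43. Astrocyte markers had a median of 0.32 (0.027; adjusted p = 0.8 with an estimated correlation) and the call ended without SBES 1 (median 0.18, 0.184), untrained 1 (0.23, 0.243) or untrained 2 (0.26, 0.08). Schwann cell markers, at 0.37 (0.0373; adjusted p = 0.8 with an estimated correlation), ended without untrained 1 (0.406), where the median was 0.11. Without SBES 1, 2 or 3 they missed the threshold (0.0735, 0.0569 and 0.0695) at medians of 0.40, 0.48 and 0.31. The Schwann cell call held in 7 of 25 other settings. It missed the threshold with a replicate block (0.054), a glial marker covariate (0.0629) or only the 6 libraries compared (0.0991), at medians of 0.32, 0.31 and 0.28. Without a filter on low counts (0.0811) the median was 0.22. The call was also lost with limma on FPKM or TPM (0.303 to 0.391), at medians of -0.07 to 0.13, and with array weights (0.879), at -0.12.

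The comparison of SBES with sham libraries sets stimulated injured mice against sham mice. Here 55 genes changed with edgeR (n = 3 libraries per group), 43 higher and 12 lower, with a median absolute log2 fold change of 2.35. Among those that rose were Itgad, an integrin subunit of macrophages (18.2-fold), Cdkn1a, which encodes the cell cycle inhibitor p21 (11.6-fold), Sult1a1 (10.2-fold), Nfkbia, the inhibitor of NF-kappaB (4.66-fold), and Per1 (5.32-fold). The size of the Cdkn1a rise depended on SBES 3, the only library at 20 Hz, with 1517 CPM where SBES 1 and 2 had 436 and 377 CPM. Among those that fell were Gkn3 (10.9-fold lower), Calca (5.82-fold lower) and 2 genes of oligodendrocytes, Ugt8a (5.01-fold lower) and Car2, a carbonic anhydrase (3.31-fold lower). The fold of Gkn3 rests on low SBES levels, 0.78, 1.39 and 0.25 CPM in SBES 1, 2 and 3. The count at an unadjusted p under 0.05 was 1480, 906 higher and 574 lower. DESeq2 called 281 genes, which included all 55. Libraries of the 2 groups did not overlap for 13.8% of genes, where chance gives 10%. Without sham 3 edgeR called 0 of the 55 (and 0 genes in all, with 954 at an unadjusted p under 0.05), without SBES 3 it called 4 genes and without sham 2 it called 6; all 55 kept their direction in these fits, with medians of 2.24, 2.22 and 2.45 in the direction of the call. The count was 28 without sham 1, 24 without untrained 2, 87 without SBES 1 and 575 without the 3 replicate 1 libraries, a fit chosen after seeing the data. Sham 3, without which none of the 55 passed, was also the library with 13.3 CPM of Xist, transcribed from the inactive X chromosome of females, and 0.339 CPM of Ddx3y, a gene of the Y chromosome, where the other libraries had at most 1.38 and at least 10.8 CPM. Of the 45 lists 13 passed camera, 0 with an estimated correlation or with fry, and the other splits of the same 6 libraries gave 8 to 24.

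The gene with the smallest adjusted p was Sult1a1 (ENSMUSG00000030711, chromosome 7, 126672865 to 126676432, minus strand), which overlaps Sgf29 on the other strand. It stood at 104 ± 29.8 CPM in SBES against 10.1 ± 3.59 in sham (log2 fold change 3.35, SE 0.39, edgeR adjusted p = 0.00953). Itgad (chromosome 7) rose from 1.82 ± 0.413 to 32.6 ± 9.12 CPM (4.19, SE 0.58, adjusted p = 0.0149). The gene overlaps 5 others, among them Cox6a2 on the other strand and 1, the predicted gene Gm17831, on the same strand. Setdb2 rose from 1.45 ± 1.26 to 22.2 ± 9.60 CPM (3.85, SE 0.58), Phactr3 from 27.4 ± 3.43 to 237 ± 117 CPM (3.11, SE 0.43) and Cdkn1a from 67.1 ± 12.2 to 776 ± 642 CPM (3.53, SE 0.61). Arrdc2, an alpha-arrestin (2.87, SE 0.46), Ada, adenosine deaminase (2.81, SE 0.38), and Tekt4, a tektin of cilia (2.79, SE 0.50), completed the 8 largest rises that met the limits for naming. The falls were led by Gkn3 (-3.45, SE 0.49), at 0.805 ± 0.570 against 8.77 ± 1.98 CPM, Calca (-2.54, SE 0.41), at 59.3 ± 21.5 against 345 ± 177 CPM, and Ugt8a (-2.33, SE 0.32), at 14.1 ± 1.33 against 70.5 ± 14.9 CPM. Cox7a1 (-2.26, SE 0.38), Serpinb1a (-2.16, SE 0.34), Bfsp2, a beaded filament gene known from the lens (-1.97, SE 0.32), Car2 (-1.73, SE 0.30) and Chn2, a GTPase-activating protein for Rac (-1.28, SE 0.23), also fell.

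**Figure D2:**
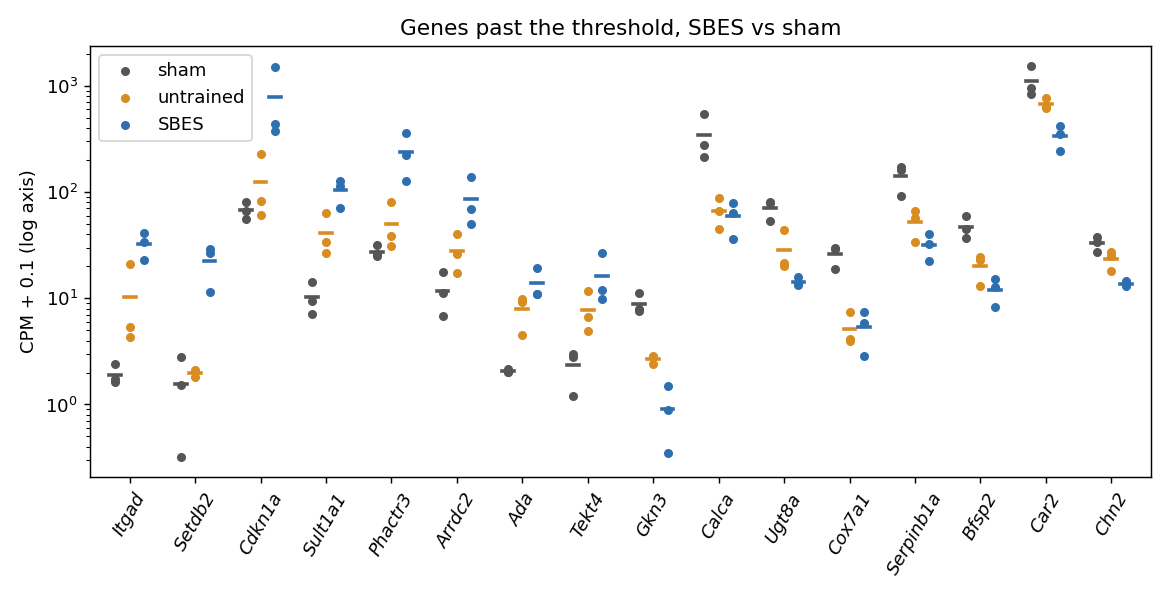
TMM-scaled CPM of genes called with edgeR in SBES against sham, plus 0.1, on a log axis, with a point per library and a bar at the mean of each group of 3. Sult1a1 averages 10.1 CPM in sham, 41.3 in untrained and 104 in SBES libraries, and Calca averages 345, 65.9 and 59.3.

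Untrained libraries lay between the sham and the SBES mean in 54 of the 55 called genes. In the direction of the call, the median log2 fold change was 1.09 from sham to untrained and 1.14 from untrained to SBES. For the 55 genes of smallest p, simulated unchanged groups gave 85.6% between (76.4% to 92.7% over 20 simulations), and the libraries 98.2%. Group labels drawn anew for the same libraries gave a mean of 80.3%, and 5 of 100 draws were as high.

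Of the activity-dependent immediate early list, 3 of 31 members rose over all genes tested and 30 were positive (median 0.85, camera adjusted p = 2.28e-12; adjusted p = 0.172 with an estimated correlation). These were Per1 (2.41, SE 0.38), Maff (2.61, SE 0.47) and Zfp36 (2.15, SE 0.40). Adjusted over the list alone 11 rose and 1 fell, Arc, a gene of synapses, at -1.32. Of the PI3K-Akt-mTOR list (0.000184; adjusted p = 0.366 with an estimated correlation) 2 rose over all genes, Ddit4 (2.36, SE 0.30) and the transcription factor Foxo3 (1.85, SE 0.34), and 5 adjusted over the list alone. These members are inhibitors of the pathway or are restrained by it. The regeneration-associated list had a median of 0.30 (0.000645; adjusted p = 0.67 with an estimated correlation), and 8 of 35 rose adjusted over the list alone, 0 over all genes. Cebpd stood at 3.12 (SE 0.61), Ecel1 at 1.34 (SE 0.27) and Cebpb at 2.08 (SE 0.53), and Cebpd and Cebpb at 1.91 and 1.16 without SBES 3. The median of this list was 0.73 without sham 1, and that of the PI3K-Akt-mTOR list was 0.23, with 0.38 without sham 1, 0.08 without SBES 1 and 0.36 without SBES 2. In the apoptosis list Cdkn1a and the death receptor Fas (1.51, SE 0.27) rose over all genes and 4 adjusted over the list alone (0.0291; adjusted p = 0.67 with an estimated correlation). In the cytokine and chemokine list (0.0127; adjusted p = 0.845 with an estimated correlation) 1 rose over all genes, Nfkbia (2.22, SE 0.34), and 3 adjusted over the list alone, with the receptors Il6ra at 1.85 and Il1r1 at 1.94. The apoptosis list, with a median of 0.28, missed the threshold without sham 1 or SBES 3 (0.134 and 0.224) at medians of 0.25 and 0.27, and without SBES 2 (0.176) at 0.15. The cytokine call, at a median of 0.12, ended without sham 2 (-0.07, 0.124) or sham 3 (0.00, 0.29), and without SBES 3 (0.063) the median was 0.12. It was 0.81 without sham 1 and 0.03 without SBES 1. Both calls were also lost with limma on FPKM or TPM, at adjusted p of 0.0734 to 0.19 and of 0.0543 to 0.261, and the cytokine call with a stricter filter (0.0883).

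Among markers of other cells, endothelial and pericyte genes were higher (median 0.22, 18 of 21 positive, camera adjusted p = 0.000149; adjusted p = 0.67 with an estimated correlation). The median was 0.07 without sham 3 (adjusted p = 0.0177), 0.42 without sham 2 and 0.34 without SBES 1. The clotting factor gene Vwf (2.28, SE 0.41) and Slc2a1 (1.56, SE 0.27) rose over all genes, and 5 adjusted over the list alone, while Cldn5, of the tight junctions of vessels, was at 117 ± 52.4 against 109 ± 28.5 CPM. MHC class I and complement genes were higher (median 0.52, 1.45e-05; adjusted p = 0.67 with an estimated correlation), with 0 over all genes and 2 adjusted over the list alone, C1ra (2.61) and C5ar1 (2.18). Their median was 1.53 without sham 1, 0.79 without SBES 1, 0.27 without sham 3, 0.32 without SBES 2 and 0.31 without SBES 3. Oligodendrocyte and myelin genes were lower (median -0.31, 8.27e-06; adjusted p = 0.67 with an estimated correlation), with 2 over all genes and 5 adjusted over the list alone, such as Ermn at -1.11 (SE 0.25), and a median of -0.19 without SBES 2 and -0.66 without SBES 3. Members of the list differed in sign, and Mbp was at 54694 ± 13327 against 63344 ± 27969 CPM. Motor neuron markers were lower (median -0.16, 0.0206; adjusted p = 0.986 with an estimated correlation), with Calca over all genes and 5 adjusted over the list alone, including Uts2b at -3.97 (SE 0.82) and Chodl, a marker of fast motor neurons, at -1.30 (SE 0.32). That call ended without sham 2, sham 3 or SBES 2 (0.0533, 0.101 and 0.156), where the median was -0.06, -0.07 and -0.01.

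Cholesterol biosynthesis genes were lower (24 of 25 negative, median -0.80, camera adjusted p = 2.61e-13; adjusted p = 0.623 with an estimated correlation), with 0 over all genes and 12 adjusted over the list alone, such as Mvd (-1.53, SE 0.34) and Msmo1 (-1.38, SE 0.32). All 75 nuclear-encoded oxidative phosphorylation genes were negative (median -0.42, 2.66e-09; adjusted p = 0.67 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. Without sham 1 their median was -0.11 (adjusted p = 0.0101). Heat shock genes had a median of -0.36 (0.0224; adjusted p = 0.366 with an estimated correlation), and neurofilament and axonal cytoskeleton genes one of -0.17 (0.019; adjusted p = 0.986 with an estimated correlation), with 0 members passing adjusted over the list alone. The heat shock list missed the threshold without sham 3 or SBES 2 (0.0769 and 0.261) at medians of -0.32 and -0.26, and also with a stricter filter (0.0611), limma on FPKM or TPM (0.0543 to 0.158, though 0.0328 without a mean trend) and array weights (0.143). The cytoskeleton call ended without sham 1 or SBES 2 (0.101 and 0.791) at -0.06 and -0.07, and the median was -0.27 without sham 2 and -0.41 without SBES 1.

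**Figure D3:**
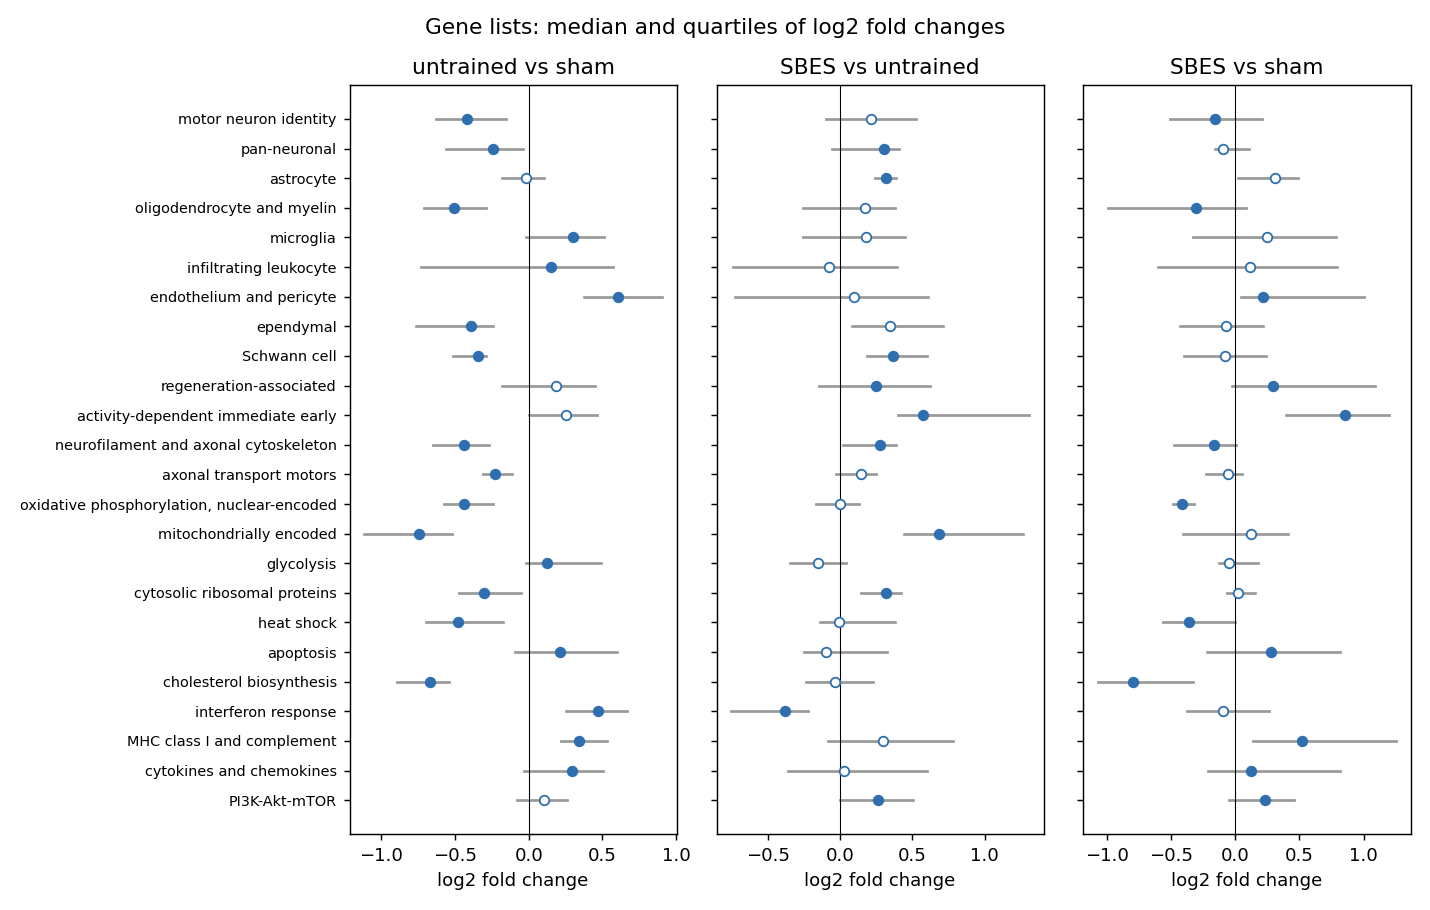
Median (point) and quartiles (line) of the log2 fold changes of the members of gene lists called in at least 1 of the 3 comparisons, with filled points for lists that passed camera. Cholesterol biosynthesis stands at -0.67 in untrained against sham and -0.80 in SBES against sham, and the immediate early list at 0.85 in SBES against sham.

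Whether stimulation turned back the injury's changes was asked with the genes and lists called in both comparisons that share the untrained libraries. With edgeR 0 genes were called in either comparison, so no gene could be called in opposite directions. The counts at an unadjusted p under 0.05 were 707 and 854, DESeq2 called 14 and 29 genes with 0 in opposite directions, and edgeR without a filter on low counts called 15 genes in opposite directions. Across genes, which are not independent replicates, the log2 fold changes of injury and stimulation had a covariance of -0.0393, against -0.0962 in simulated unchanged groups and -0.116 on average over 100 draws of new group labels for the same libraries, of which 92 were as low. Their correlation was -0.188, against -0.489 and -0.495. Of the gene lists, 6 were called in both, all in opposite directions. The simulations, which draw each gene separately, gave 0.05 on average, but the draws of new labels gave 6.92 (0 to 20), and 56 of the 100 gave at least 6. The count of opposite lists was therefore no higher than that of labels drawn anew. The pan-neuronal, Schwann cell, neurofilament, mitochondrially encoded and ribosomal protein lists fell after injury and rose with stimulation, and the interferon list rose and fell. With an estimated correlation both interferon calls were lost (adjusted p = 0.188 and adjusted p = 0.116), as were all the others. At the preset correlation the interferon list kept both calls when any single library was left out, the pan-neuronal and neurofilament lists kept only the call after injury, the ribosomal list only the call with stimulation, and the Schwann cell and mitochondrially encoded lists neither. Without sham 1 the ribosomal call after injury ended (adjusted p = 0.407) and without SBES 1 the pan-neuronal and neurofilament calls with stimulation ended (0.78 and 0.859). The 3 untrained libraries are too few to split between the comparisons. Sharing them alone gave covariances of -0.101 to -0.0936 in the 20 simulations, all lower than the observed -0.0393. The opposition across genes was therefore no larger than sharing the untrained libraries gives, and it does not show a reversal by stimulation.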

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

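The alternatives named here with the replicate 1 libraries left out or given a term of their own, and those of the principal components, were chosen after the results were seen. The counts of called genes depended on the tool, the filter and single libraries, and the cause was not tested except where fewer genes were tested or where the values of 1 library are given. DESeq2 called 14 genes in untrained against sham, 29 in SBES against untrained and 281 in SBES against sham. Without a filter on low counts edgeR called 134, 186 and 517, with 15 genes called in opposite directions by injury and stimulation. Of these calls 127, 177 and 498 were of genes that the filter had kept, so most were not low-count genes added to the test. In SBES against sham, a stricter filter that tested fewer genes gave 23 calls, limma on log2(FPKM + 1) gave 19, a pseudocount of 0.1 gave 17, TPM 17, quantile normalization 28, median-of-ratios rescaling 35 and limma without a mean trend 7. Limma on log2(FPKM + 1) called 1 gene in SBES against untrained, and a pseudocount of 0.1 gave 1 in untrained against sham. On FPKM the median of all genes was shifted by 0.14, -0.17 and -0.03, and on TPM by 0.21, -0.28 and -0.07, in the order of the comparisons above. Limma with array weights called 2, 50 and 35 genes and 6 lists in SBES against untrained, but its weights did not converge and sham 3 had a weight of 0.000431, so it was almost left out. The 55 genes called in SBES against sham kept their direction in every alternative in which they were tested. Deviations from the group means correlated over 0.1 in 7 of the 9 pairs of libraries with the same replicate number, the 3 of replicate 1, the 3 of replicate 3 (together 0.14 to 0.39) and sham 2 with SBES 2 (0.159), and in 5 of the 18 with different numbers (median -0.126). The other pairs of replicate 2 had 0.00105 (sham with untrained) and -0.168 (untrained with SBES), and 4 of the 9 libraries matched one of their own number best, so the numbers were not taken as pairs; a replicate block gave 4 calls in untrained against sham and 132 in SBES against sham, including all 55. A term for replicate 1 gave 9 in untrained against sham and 186 in SBES against sham, and leaving out the 3 replicate 1 libraries gave 47, 13 and 575.

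When each library was left out in turn, called genes ranged from 0 to 0 in untrained against sham, from 0 to 1 in SBES against untrained and from 0 to 87 in SBES against sham. Called lists ranged from 16 to 25, from 5 to 18 and from 9 to 19. SBES against untrained had 18 called lists without untrained 1 or without SBES 3 and 5 without SBES 1. SBES against sham had 0 called genes without sham 3, 4 without SBES 3, 6 without sham 2, 24 without untrained 2, 28 without sham 1 and 87 without SBES 1. Where a group was left with 2 libraries, they were assumed to vary like the others. With an estimated correlation camera called 0, 0 and 0 lists, and with fry, on its directional p, 0, 0 and 0. The median of the mitochondrially encoded list in untrained against sham was 0.1907 with array weights and 0.2432 without the replicate 1 libraries, and ranged from -1.178 to 0.3079 without single libraries. In SBES against untrained it was -0.1163, -0.1921 and from -0.1884 to 0.9931. The neurofilament and axonal cytoskeleton list in SBES against untrained was -0.122, -0.09623 and from 0.04107 to 0.4332, and ribosomal proteins in untrained against sham were at 0.04791 with array weights. Without the replicate 1 libraries the log2 fold change of Gpnmb in untrained against sham turned to 2.881, and those of S100a8, S100a9 and Hba-a2 in SBES against sham to 3.385, 3.282 and 2.084. Leaving out sham 1 alone turned them as well (2.605, 3.317, 3.044 and 1.894), since sham 1 stood at 75.4, 1009, 411 and 82.3 CPM and sham 2 and 3 at no more than 2.13, 12.4, 6.79 and 8.07. List calls kept in fewer than 18 of 26 settings were those of apoptosis in both comparisons with sham (15 and 15), cytokines (14) and heat shock (15) in SBES against sham, mitochondrially encoded genes in untrained against sham (17), and neurofilament (15) and astrocyte (17) in SBES against untrained; the Schwann cell call of SBES against untrained was kept in 7 of 25. Limma on FPKM or TPM, a stricter filter and left-out libraries ended most of these, and array weights, the glial covariate or leaving out replicate 1 ended some. Calls kept more often had losses too. Array weights ended the oligodendrocyte calls against sham (untrained, camera adjusted p = 0.0644, and SBES, 0.0889) and the endothelial call in SBES against sham (0.228, median 0.01). Quantile normalization and median-of-ratios rescaling ended the motor neuron call in SBES against sham (0.062 and 0.0581). They also ended the Schwann cell call in untrained against sham (0.194 and 0.0745). The first principal component held 37.76% of the variance with a pseudocount of 0.1, 48.28% on TPM, 30.88% after quantile normalization, 37.05% without a filter, 48.78% with a stricter filter, 28.52% on TMM-scaled log2 CPM, and from 37.83% to 49.07% without single libraries.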

Other observations

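The tests of vessel cells and their spread, of the replicate 1 libraries as a source of the called genes and of RNA from glial cells, and the spreads over libraries, were chosen after the result was seen, as were the glucocorticoid and clock gene lists, though what their tests should show was written before they were run. Gene lists for the receptors and channels of neurons passed camera in none of the 3 comparisons. Glutamate receptors had medians of -0.05, 0.19 and 0.12 in untrained against sham, SBES against untrained and SBES against sham (camera adjusted p = 0.888, 0.23 and 0.573). Potassium channels stood at -0.05, 0.11 and 0.09 (0.314, 0.0901 and 0.696), and receptors for GABA and glycine with chloride transport at 0.01, 0.05 and 0.03 (0.888, 0.964 and 0.899). Axon guidance genes had medians of -0.16, 0.21 and 0.08 (0.0873, 0.0527 and 0.809), and neurotrophic factors and receptors of -0.02, 0.16 and 0.20 (0.908, 0.336 and 0.514). Markers of spinal interneurons had medians of 0.26, -0.29 and 0.12 (0.963, 0.858 and 0.864).

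Astrocyte markers were among the more abundant transcripts, with Gfap at 2239 ± 756 CPM (SD, n = 3) in sham, 2236 ± 1292 in untrained and 2889 ± 1387 in SBES, and the glutamate transporter gene Slc1a2 at 233.9 ± 53.5, 181.0 ± 67.2 and 232.5 ± 70.9. The microglial genes Aif1 and Cx3cr1 stood at 41.0 ± 25.1 and 52.6 ± 37.0 CPM in sham and at 25.2 ± 6.44 and 38.0 ± 5.72 in SBES. The higher sham means rest on sham 1, at 69.9 and 95.3 CPM. Sham 2 and 3 had 24.4 and 28.7 CPM of Aif1 and 31.0 and 31.5 CPM of Cx3cr1. Other microglial genes differed in sign between SBES and sham, with C1qa higher and Gpr34 lower by their means. Gad1, of inhibitory neurons, was at 40.3 ± 14.9 CPM in sham, and Slc17a6, of excitatory neurons, at 44.4 ± 8.43. The labels give no sex for the mouse of sham 3, the library with Xist and almost no Ddx3y, without which edgeR called 0 genes in SBES against sham (954 at an unadjusted p under 0.05).

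The 25 glucocorticoid-induced genes were tested in all 3 comparisons, with adjustment over 9 tests. Their median log2 fold change was 0.15 in untrained against sham (19 positive; camera adjusted p = 0.375 with an estimated correlation), with 0 rising adjusted over the list alone. This median depended on single libraries. Without untrained 1 it was 0.41, with 23 positive and an unadjusted camera p of 0.0409 with an estimated correlation. Without untrained 3 it was 0.05, with 14 positive, and without the 3 replicate 1 libraries 0.34, with 22 positive (unadjusted p = 0.181). In SBES against untrained it was 0.96 (24 positive; adjusted p = 0.0248 with an estimated correlation), with 8 rising adjusted over the list alone and 0 over all genes with edgeR (13 at an unadjusted p under 0.05). Without the 3 replicate 1 libraries the unadjusted p of this comparison was 0.0728, at a median of 0.69. None of the 45 lists fixed before the data were examined passed with an estimated correlation, and this list was chosen after genes of SBES against sham had been seen, which shares the SBES libraries.

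Several genes called in SBES against sham, such as Per1, Ddit4, Nfkbia and Cdkn1a, are known targets of glucocorticoids, and a glucocorticoid response may lie behind part of the calls, as a hypothesis. The list of 25 other glucocorticoid-induced genes had a median log2 fold change of 1.194, with 23 positive (camera p = 0.00511 with an estimated correlation, 0.0248 adjusted over 9 tests). Of its members 15 rose adjusted over the list alone and 0 over all genes with edgeR, and 16 had an unadjusted p under 0.05. Fkbp5 stood at 2.38, and at 1.32 in untrained against sham. Tsc22d3 stood at 0.72 (SE 0.46), and at -0.007 in untrained against sham, while Litaf (-0.34) and Lpin1 (-0.06) were negative in SBES against sham. Without the replicate 1 libraries the median change of the called genes was 2.482 in the direction of the call. The groups' libraries did not overlap for any of the 55 called genes, which all but fixed their direction. The value therefore cannot rule out the replicate 1 libraries as a cause. The median of the endothelial list was 0.2159 (interquartile range 0.955, jackknife SE over libraries 0.269), where the smallest change among genes called higher was 1.32. Those genes were picked for large changes, so the comparison cannot exclude more vessel cells. The upper quartile of the list ran from 0.641 to 1.28 without single libraries (jackknife SE 0.496). A change within vessel cells stays open as well. Time of day stays open, since clock output and clock activator genes differed by 0.4167 (jackknife SE over libraries 0.461). With an estimated correlation, the clock output list had camera adjusted p = 0.236 over 9 tests in SBES against sham, with 5 of 8 positive. That list rose in untrained against sham (adjusted p = 0.0412, 7 of 8 positive), with 0 members passing over the list alone. In SBES against untrained 3 of 8 were positive (adjusted p = 0.436). Without single libraries the estimated p of the glucocorticoid list ran from 0.00357 to 0.0253, without the replicate 1 libraries it was 0.0492, and stress of handling or anaesthesia was not separable from stimulation and stays untested.

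The replicate 1 libraries stood apart on the first principal component, and the 1777 genes that edgeR called between them and the others restate that separation, since these libraries were picked by it. More nuclear RNA may contribute, since nuclear-retained noncoding RNAs without Malat1 had a median log2 fold change of 1.579 in replicate 1, with 8 of 8 positive (camera adjusted p = 0.147 with an estimated correlation for the list with Malat1). It would not raise mitochondrially encoded genes, which were higher in sham 1 and SBES 1 (mean log2 CPM 9.76 and 9.81) but not in untrained 1 (7.77, with 8.25 and 7.73 in untrained 2 and 3; list adjusted p = 0.424 with an estimated correlation), so that rise is not shared by the 3 libraries. Lists of glutamate receptors (median 0.63), sodium channels (0.69) and calcium channels (0.54) were also higher at the preset correlation, and lost that with an estimated correlation (adjusted p = 0.104, 0.276 and 0.147). Other lists did the same, such as red blood cell (2.15), spinal interneuron (0.83), nuclear-encoded oxidative phosphorylation (0.50) and ribosomal protein genes (0.34). Lower at the preset correlation only were cholesterol biosynthesis (-0.36), apoptosis (-0.31), oligodendrocyte (-0.26) and motor neuron genes (-0.20). A gene length bias stays open, at a Spearman rho of 0.2036 across genes, which are not independent replicates. No biological explanation was tested.

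Markers of oligodendrocytes exceeded motor neuron markers in 9 of 9 libraries by their median level, although labelled neurons were aspirated with electrodes. RNA from glial cells may be the source, as a hypothesis, but the oligodendrocyte median exceeded that of pan-neuronal markers (202 to 394 CPM) in only 5 of 9 libraries, so the levels leave it open. Of the 24 oligodendrocyte genes 3 are in another list, and Mbp took at least 3.40% of counts in each library. The level of motor neuron transcripts in a pure sample is not given in the sources used here, so the share of glial RNA was not estimated.

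For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In untrained against sham 10 splits gave as many genes as the real one (0, highest other 0, with 707 at an unadjusted p under 0.05 and 14 by DESeq2) and 2 gave as many lists (20, highest other 20). In SBES against untrained 10 gave as many genes (0, highest other 0, with 854 and 29) and 10 as many lists (10, highest other 24). In SBES against sham 1 gave as many genes (55, highest other 7) and 6 as many lists (13, highest other 24). The splits with 24 lists put SBES 1 with untrained 1 or with sham 1, which points to a structure of the samples other than the groups.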
